A study of Solanum lycopersicum and Solanum pennellii with 32 samples.

How the data were processed

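Per the labels' protocols, seedlings with a 35S:TRAP construct were grown at 25 degrees Celsius in 12 hours of light, on a medium with or without added phosphate, and harvested 8 to 10 days after germination. A TRAP construct expresses a tagged ribosomal protein, but the labels describe extraction of total RNA, and the values are treated here as total RNA. Libraries were made with BrAD-seq, a strand-specific method that reads the 3' ends of transcripts, and sequenced as single reads of 50 bases. Reads of a 3' method do not scale with transcript length, so no length correction was applied.

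The deposited tables hold estimated counts per gene model, partly fractional, for 34843 IDs in each of 2 tables, one per species. Per the submitters' processing notes, FastQC, Bowtie 1.2.2, edgeR and limma were used. The program behind the fractional counts, the genome build and the annotation version are not given in the sources used here. The name of the Pennellii table states that its reads were mapped to M82, so Pennellii reads that differ from the M82 sequence can be lost, and levels were not compared between the species. Of all values, 6.17% were fractional, in 24.6% of the genes; what made a value fractional was not tested, and the levels of such genes are treated as uncertain. Each column name carried the code that the sample titles give, so all 32 columns were assigned and 0 columns were left unused. Replicates are biological replicates per the series' design text.

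The IDs were looked up in a reference table of RefSeq genes of assembly SLM_r2.1, and 0 of 34843 matched any of its names or accessions. The files pair the IDs with no names or descriptions, so genes are given by ID, without names, functions or coordinates. The gene lists chosen before the data were examined could therefore not be filled, and no test of a gene list was run. The naming rule also held 15 genes whose IDs had been paired with names from general knowledge; no source used here gives that pairing, so they are not reported, a departure from the rule. Named genes follow the rule fixed for this case: among called genes whose libraries of one group all lie above those of the other (not required for interactions), up to 2 with the largest rise and 2 with the largest fall in each comparison.

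Estimated counts were rounded to whole numbers, so a gene called absent, without a count or at 0 can hold estimates below 0.5 in a library, and libraries were scaled by TMM factors. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. Tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust dispersion estimates, Benjamini-Hochberg adjustment, threshold 0.05). All 4 groups of a species shared 1 fit, which tested 18275 genes in M82 and 13450 in Pennellii, and all groups of both species entered 1 fit of 19460 genes for the differences between species. The 10 comparisons were limiting against sufficient phosphate in each species and position, tip against midsection at sufficient phosphate in each species, and the interactions of phosphate with position and with species. Standard errors were taken as the size of the log2 fold change divided by the square root of F. Where a group holds few or no counts, they are no measure of the precision of the fold. CPM values use TMM-scaled library sizes. Where a group held no count of a gene, the fold is a lower bound, the other group's counts over its summed depth against 3 counts over the summed depth of the group without counts. With 1 to 3 counts the ratio of summed counts over summed depth is given with an exact 95% interval. Depths are TMM-scaled. Such sums weight libraries by depth, unlike the means of CPM, so both can differ where 1 library holds most of the depth. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The floor of 3 counts was 0.0947 CPM in the deepest M82 library and 180 CPM in the Pennellii library of 6225 counts.

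The design assumed 4 distinct libraries in each group. Because 2 Pennellii columns were identical, both were left out of the reported fits, a departure from that design, and alternatives kept them. The test was checked on simulated counts with the depths of the real libraries, means and dispersions over all groups of a fit, and 200 changed genes. For M82 tips it recovered 10%, 42%, 64% and 82% of genes changed 2, 4, 16 and 64-fold, and for M82 midsections 10%, 46%, 82% and 86%. For Pennellii tips it recovered 0%, 0%, 10% and 40%, and for Pennellii midsections 0%, 0%, 8% and 36%. For the interaction between species it recovered 4% of 4-fold and 56% of 64-fold changes in tips and 0% and 64% in midsections.

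Alternatives set before the data were examined were RLE scaling, DESeq2 1.42.0, limma-voom with limma 3.58.1, no low-count filter, a filter of 5 CPM in 4 libraries, the replicate number as a block, fits of only the groups compared, and each library left out in turn. Alternatives added after seeing the data were the identical columns kept in both groups or in either, only Pennellii libraries of at least 100000 counts, only M82 libraries of at least 2000000 counts, only genes with whole counts in every M82 library, and the count of genes called in both M82 positions.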

Results

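Transcript abundance was measured in roots of tomato seedlings that carried a 35S:TRAP construct, in the cultivated tomato Solanum lycopersicum M82 and in its wild relative Solanum pennellii LA0716 (called Pennellii below). Seedlings were 8 to 10 days old and had grown with sufficient or with limiting phosphate. Material was taken from a 1 cm segment at the root tip or from about 2 cm of midsection, midway along the root. The 32 libraries fell into 8 groups of 4 biological replicates, and the labels give 30 to 40 plants for each replicate. The questions were how limiting phosphate changed gene expression in each root position, and whether that response differed between positions and between species.

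Depth was uneven. In M82, the tip libraries at sufficient phosphate held 4456958, 34103546, 1553874 and 1406650 counts, and those at limiting phosphate 4806020, 4874528, 4223900 and 9737420. M82 midsections held 8454258, 9095141, 1084652 and 8498744 counts at sufficient phosphate and 11338177, 7462744, 11678167 and 5382729 at limiting phosphate. Pennellii tips held 894656, 46018, 1323408 and 6225 counts at sufficient phosphate and 4983619, 1529463, 50571 and 1859241 at limiting phosphate. Pennellii midsections held 50571, 464792, 13124725 and 6483725 counts at sufficient phosphate and 664429, 137511, 38629 and 4580524 at limiting phosphate. The limiting tip replicate 3 and the sufficient midsection replicate 1 of Pennellii had identical values in every gene. Because the labels put these 2 columns in different groups, both were left out, which left 30 libraries. The typical biological coefficient of variation was 0.599 in M82 and 1.21 in Pennellii.

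**Figure D1:**
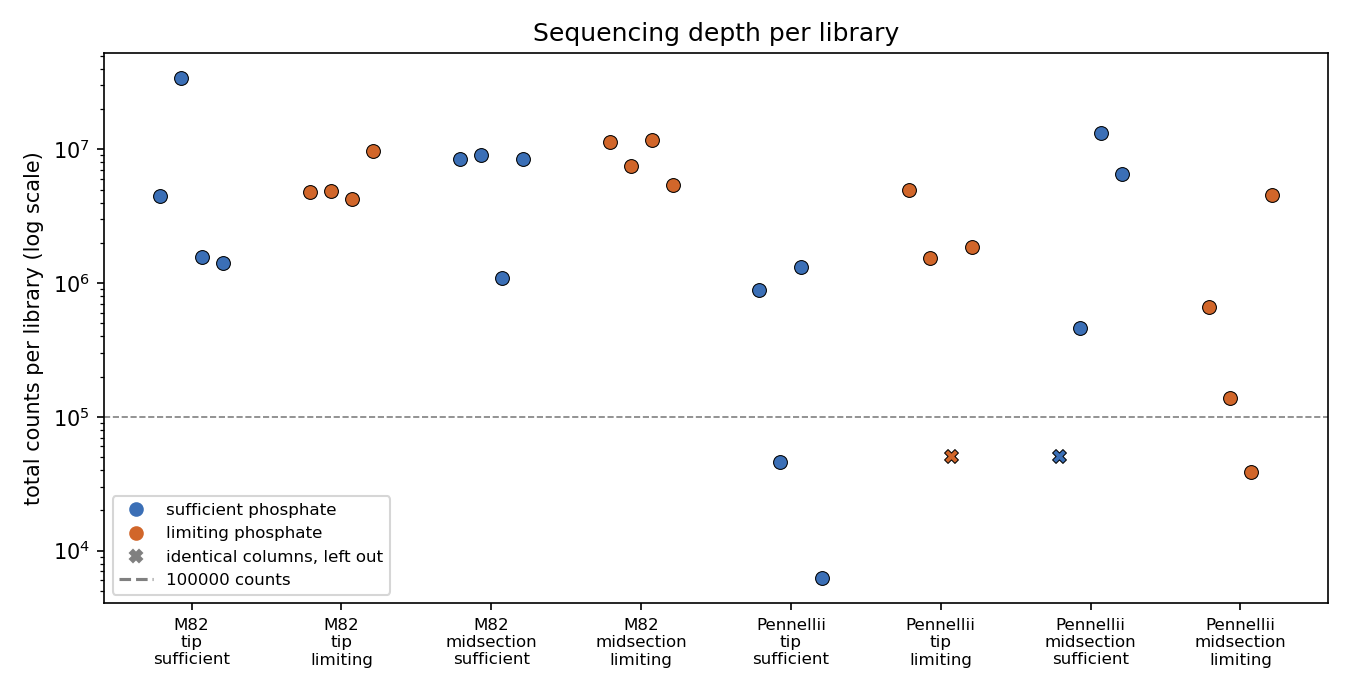
Total counts per library on a log axis, 1 point per library, for the 8 groups of 4 libraries, with the dashed line at 100000 counts. M82 libraries lie between 1084652 and 34103546 counts, whereas Pennellii libraries reach down to 6225, and crosses mark the 2 identical columns of 50571 counts.

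In M82 root tips, limiting phosphate raised many more transcripts than it lowered. Of 18275 genes tested, 223 rose and 37 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 4 and 4), and 209 of those that rose did so by more than 2-fold. Solyc01g095745.1.1 had the largest rise, from 0.391 ± 0.783 CPM (SD, n = 4) at sufficient phosphate to 336 ± 76.2 CPM (SD, n = 4) at limiting phosphate. The ratio of these means is 858, but after rounding the sufficient tips held 2 counts of this gene, both in replicate 4 (2.818 in all 4 libraries before rounding). From counts over the summed depth the ratio was 6860 (95% counting interval 1900 to 56700), at least 4430 without replicate 4 and 1320 (365 to 10900) without replicate 2, the deepest library. Its log2 fold change was 12.16 ± 0.58 (SE), with an edgeR adjusted p of 5.09e-14. With 2 counts in a group this SE, derived from F, is no measure of the precision of the fold, for which the counting interval is wider. Its counts were fractional in 93.8% of M82 libraries, and its level is treated as uncertain. Solyc05g007950.3.1 was absent from the sufficient tips and averaged 8.70 ± 12.5 CPM (SD, n = 4) in the limiting tips, at least 99.8-fold higher by summed counts against a floor of 3 counts over the group, with an edgeR adjusted p of 0.0489. That bound fell to 19.2 without sufficient replicate 2 and to 44.8 without limiting replicate 3. Solyc06g008990.1.1 fell from 33.6 ± 12.8 CPM to 1.67 ± 1.28 CPM (SD, n = 4 each), with a log2 fold change of -4.32 ± 0.81 and an edgeR adjusted p of 0.00192. Solyc06g061040.3.1 fell from 5.63 ± 4.16 CPM (SD, n = 4) to 1 count in the 4 limiting libraries, with an edgeR adjusted p of 0.0482. Its means differ 222-fold and its summed counts 41.2-fold (95% counting interval 7.15 to 1650), or 138-fold without sufficient replicate 2 and at least 8.12-fold without limiting replicate 4. The calls for Solyc05g007950.3.1 and Solyc06g061040.3.1 ended under 9 and 11 of their 15 alternative settings. The groups did not overlap in 234 of the 260 called genes, and in 6.23% of all tested genes, against 2.86% expected by chance. DESeq2 called 544 genes (386 up, 158 down), limma-voom 455 (246 up, 209 down) and a fit of these 2 groups alone 157 (113 up, 44 down), so the excess of rises held in each but its size did not; without limiting tip replicate 4 the count was 173.

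In M82 midsections, 175 genes rose and 86 fell at limiting phosphate (edgeR quasi-likelihood test, adjusted p under 0.05, n = 4 and 4), of 18275 tested. Solyc06g062540.3.1 rose from 0.0929 ± 0.118 CPM to 68.8 ± 28.5 CPM (SD, n = 4 each), a ratio of summed counts of 585 with a 95% counting interval of 200 to 2840, a log2 fold change of 9.05 ± 1.04 (SE) and an edgeR adjusted p of 1.31e-06. Solyc07g009100.3.1 rose from the same 0.0929 ± 0.118 CPM to 28.7 ± 7.62 CPM, a ratio of 266 with a 95% counting interval of 90.7 to 1290 and an edgeR adjusted p of 0.00297. Without sufficient replicate 1 these ratios were 1210 and 551, and without replicate 2 they were 384 and 174. Both genes had fractional counts in part of the libraries, 56.3% and 37.5%. Solyc11g045520.2.1 fell 58.8-fold, from 49.2 ± 35.0 CPM to 0.836 ± 0.806 CPM (SD, n = 4 each), with an edgeR adjusted p of 0.000569, and 113-fold without limiting replicate 4. Solyc12g088970.1.1 fell 27.9-fold, from 22.4 ± 14.3 CPM to 0.805 ± 0.356 CPM, with an edgeR adjusted p of 0.0198 that missed the threshold under 6 of 17 alternatives. The groups did not overlap in 244 of the 261 called genes, and in 10.8% of all tested genes, against 2.86% expected by chance. Calls numbered 613 (376 up, 237 down) with DESeq2, 672 (292 up, 380 down) with limma-voom and 439 (186 up, 253 down) when these groups were fitted alone, so which direction held more genes depended on the method. The count fell to between 119 and 167 when any 1 limiting library or sufficient replicate 4 was left out.

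Part of the M82 response was common to both root positions. Of the genes tested, 34 rose in tip and midsection, where 2.14 would be shared by independent lists (Fisher's exact test, one-sided p = 3.03e-31), and 2 fell in both, where independent lists would share 0.174 (p = 0.0131). No library entered both comparisons, but both came from 1 fit and share the estimated spread of each gene. Genes are not independent either, so the lists are not independent and these p-values may overstate the evidence. Solyc06g062540.3.1 and Solyc11g045520.2.1, named above for the midsection, were in these sets, with tip log2 fold changes of 3.41 ± 0.78 and -4.00 ± 0.96 (SE). A further 5 genes were called in both positions with opposite signs, all of them up in the tip and down in the midsection. The number that independent lists would share was not computed for these, so the excess may not be limited to genes that changed in the same direction. The sign was the same in the midsection for 66.2% of tip calls and in the tip for 62.1% of midsection calls, against 49.7% of all genes. These shares were not tested. Across all 18275 genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.070. Most of these genes were not called, and noise in their fold changes lowers a correlation, so it cannot show that the responses were unrelated.

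**Figure D2:**
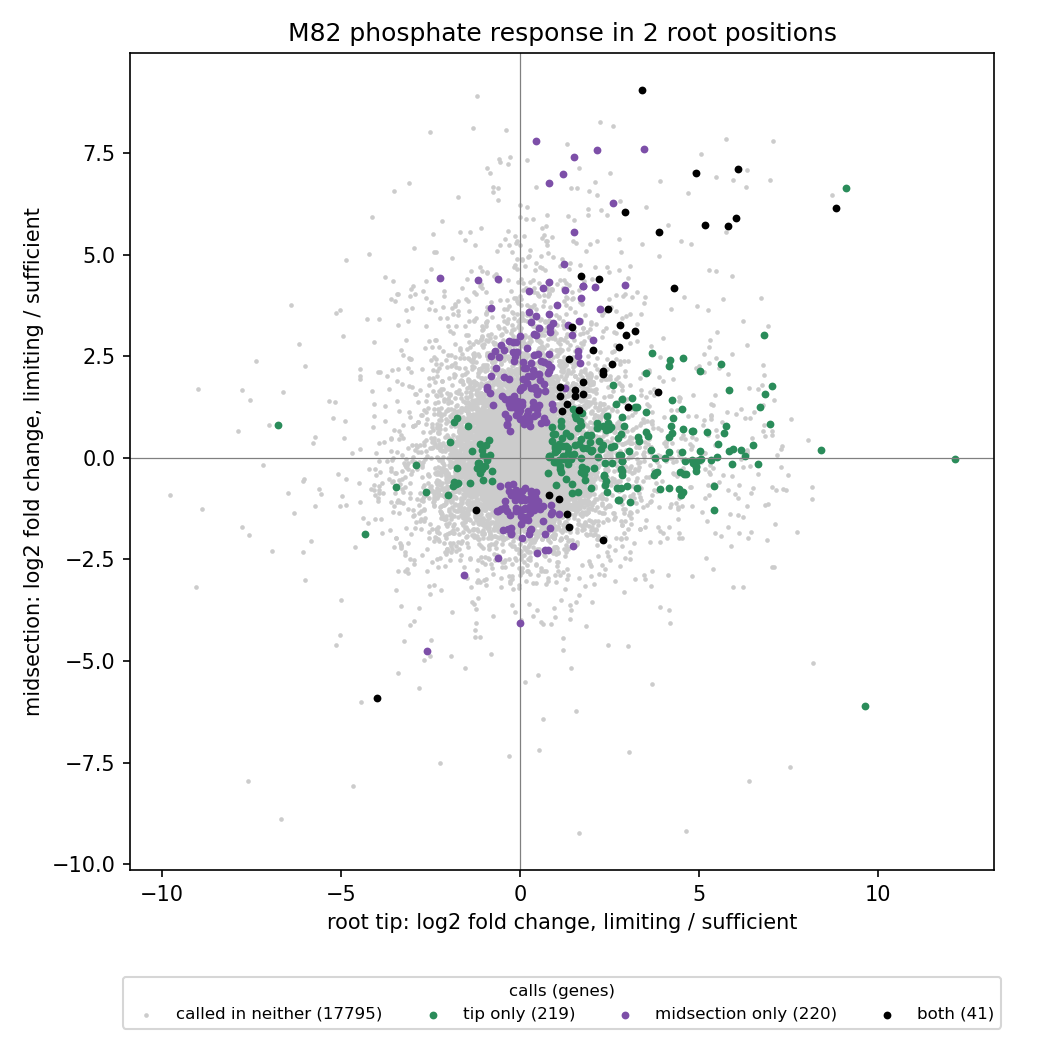
Log2 fold changes at limiting against sufficient phosphate for the 18275 genes tested in M82, tip on the horizontal axis and midsection on the vertical axis, 1 point per gene, coloured by the position in which the gene was called. The 34 genes that rose in both positions lie at the upper right.

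The response itself differed between the positions of M82 in 177 genes, 118 with a higher and 59 with a lower response in the tip (edgeR quasi-likelihood interaction test, adjusted p under 0.05, 4 groups of 4). Of the 118, 114 were called lower in the tip than in the midsection at sufficient phosphate, and of the 59, 56 were called higher. The sufficient libraries enter both tests, which by itself favours this overlap. Of the 118, 76 were also called up in the tip and 24 were called down in the midsection. Of the 59, 40 were called up in the midsection and 8 were called down in the tip, and 34 of the 177 were called in neither position alone. Solyc07g009100.3.1, which rose in the midsection, belonged to the 59. It averaged 3.38 ± 4.48 CPM and 4.16 ± 2.89 CPM (SD, n = 4 each) in sufficient and limiting tips. By summed counts over summed depth it stood at 0.586 and 4.44 CPM there, so whether it rose in tips depends on the measure. Its interaction log2 change was -7.34 ± 1.78 (SE), edgeR adjusted p 0.0342. Solyc06g035610.3.1 (-8.96 ± 2.25, edgeR adjusted p 0.046) also had a lower response in the tip, with a mean of 21.4 ± 37.6 CPM (SD, n = 4) in sufficient tips that came mostly from 1 library at 77.5 CPM. Solyc01g111160.3.1 (15.75 ± 3.00, edgeR adjusted p 0.00808) had a higher response in the tip, being absent from sufficient tips, at 12.5 ± 9.64 CPM in limiting tips, at 17.3 ± 15.9 CPM in sufficient midsections and at 0.206 ± 0.412 CPM in limiting midsections (SD, n = 4 each). Solyc07g064100.1.1 (15.17 ± 3.71, edgeR adjusted p 0.0427) followed the same order at lower levels, with counts in 2 limiting tips and 2 sufficient midsections. Fitted changes of genes absent from a group depend on the prior count and are no measure of size. These 4 genes had fractional counts in 31.3% to 62.5% of M82 libraries, and the calls for Solyc07g009100.3.1, Solyc06g035610.3.1 and Solyc07g064100.1.1 ended under 13 of 23, 16 of 23 and 13 of 19 alternatives. DESeq2 called 546 genes; leaving out 1 library gave 100 (without limiting midsection replicate 3) to 289 (without sufficient midsection replicate 1), with 110 without limiting midsection replicate 2 and 113 without sufficient midsection replicate 4.

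Position along the root separated many more M82 genes than phosphate did. At sufficient phosphate 4992 of 18275 genes differed between tip and midsection, 2496 higher and 2496 lower in the tip (edgeR quasi-likelihood test, adjusted p under 0.05, n = 4 and 4), and the groups did not overlap in 3799 of them, and in 24.3% of all tested genes, against 2.86% expected by chance. Solyc03g115380.2.1 was 1620-fold higher in the tip, at 546 ± 240 CPM against 0.336 ± 0.519 CPM (SD, n = 4 each; edgeR adjusted p 3.3e-10), and the means differed 6940-fold without midsection replicate 1. Solyc12g011455.1.1 averaged 23.3 ± 16.9 CPM (SD, n = 4) in the tip and had no count after rounding in the midsection, at least 198-fold higher (edgeR adjusted p 0.00174), or 130-fold without midsection replicate 2. Solyc01g095745.1.1, the gene that rose most with limiting phosphate in the tip, averaged 626 ± 55.0 CPM (SD, n = 4) in sufficient midsections, 1600 times its mean in sufficient tips (edgeR adjusted p 8.46e-15). By summed counts the ratio was 12300 (95% counting interval 3390 to 101000), 2350 without tip replicate 2 and at least 7900 without tip replicate 4. Solyc05g051360.1.1 had no count in sufficient tips and 42.9 ± 23.3 CPM (SD, n = 4) in midsections, at least 572-fold more (edgeR adjusted p 8.96e-08), or 110-fold without tip replicate 2. All 4 had fractional counts in 50.0% or more of the M82 libraries. A fit of these 2 groups alone called 3272 genes (1586 higher, 1686 lower).

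In Pennellii tips, 41 genes rose and 51 fell at limiting phosphate of 13450 tested (edgeR quasi-likelihood test, adjusted p under 0.05, 3 limiting and 4 sufficient libraries). The groups did not overlap in 23 of the 92 called genes, and in 8.17% of all tested genes, against 5.71% expected by chance. Solyc03g117630.1.1 had no count after rounding in the sufficient tips and averaged 425 ± 445 CPM (SD, n = 3) in the limiting tips, at least 204-fold higher by summed counts against a floor of 3 counts over the group (edgeR adjusted p 6.28e-06). That bound was 121 and 86.9 without sufficient replicates 1 and 3, and 365 and 120 without limiting replicates 1 and 4. Solyc10g006900.3.1 had none there either and averaged 299.7 ± 499.5 CPM (SD, n = 3), with an edgeR adjusted p of 0.0014, and 953 of its 1039 counts came from limiting replicate 4. It was at least 103-fold higher with that library and at least 9.95-fold without it; the bound was 61.1 and 43.8 without sufficient replicates 1 and 3, and 274 without limiting replicate 1. Solyc12g100300.2.1 fell from 82.4 ± 79.2 CPM (SD, n = 4) to 1 count in 3 libraries (edgeR adjusted p 0.0392). Its means differ 373-fold and its summed counts 769-fold (95% counting interval 137 to 30500), or 278 and 1430-fold without sufficient replicates 1 and 3, 268-fold without limiting replicate 1 and at least 204-fold without limiting replicate 2. In sufficient tips 179 of its 228 counts came from replicate 1, and the other libraries stood at 32.6 to 60 CPM. In replicates 2 and 4 that is below the floors of 97.9 and 180 CPM, so the separation of the groups rests in part on such values. Solyc09g011160.3.1 averaged 521 ± 934 CPM (SD, n = 4) in the sufficient tips, a mean set by the library of 6225 counts, and 15.6 ± 8.39 CPM (SD, n = 3) in the limiting tips (edgeR adjusted p 0.0296); the ratio of these means was 33.5, or 3.50 without that library. Solyc03g117630.1.1 and Solyc09g011160.3.1 had fractional counts in 78.6% and 92.9% of Pennellii libraries. The calls for these 4 genes, in the order given, ended under 1 of 18, 2 of 16, 7 of 18 and 7 of 18 alternatives. The median of all fitted log2 changes lay at 0.51, or 0.35 with only libraries of at least 100000 counts, and RLE scaling moved it to 0.17 and the calls to 27 up and 110 down. Of the 35 splits of these libraries into groups of 3 and 4, 19 called as many genes. Calls numbered 12 (10 up, 2 down) with only libraries of at least 100000 counts, 6 without limiting replicate 4, 29 without sufficient replicate 2, 186 and 189 without limiting replicates 1 and 2, 43 with DESeq2 and 0 with limma-voom, where 1164 genes had an unadjusted p under 0.05.

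In Pennellii midsections, 15 genes rose and 1 fell at limiting phosphate (edgeR quasi-likelihood test, adjusted p under 0.05, 4 limiting and 3 sufficient libraries, 13450 genes), and 486 had an unadjusted p under 0.05. The groups did not overlap in 3 of the 16 called genes, and in 5.83% of all tested genes, against 5.71% expected by chance. Solyc08g079160.3.1 averaged 209 ± 333 CPM (SD, n = 4) against 1.34 ± 1.49 CPM (SD, n = 3), with an edgeR adjusted p of 0.0469. Solyc07g042190.3.1 averaged 735 ± 1252 CPM (SD, n = 4) against 20.5 ± 13.2 CPM (SD, n = 3), with an edgeR adjusted p of 0.0275. Both limiting means were set by replicate 3, a library of 38629 counts that held 705 and 2610 CPM of these genes. The ratios of the means were 156 and 35.9, or 32.9 and 5.38 without that library, and the first was 386 without sufficient replicate 3. Solyc01g111350.3.1 fell from 237 ± 246 CPM (SD, n = 3) to 2.86 ± 5.72 CPM (SD, n = 4), with an edgeR adjusted p of 0.00421. Its ratio of 83 fell to 33.8 without sufficient replicate 2 and to at least 21.4 without limiting replicate 4. The calls for these 3 genes ended under 9 of 18, 8 of 18 and 5 of 17 alternatives. Calls numbered 5 (3 up, 2 down) with only libraries of at least 100000 counts, 2 without limiting replicate 3, 10 without limiting replicate 4, 25 without limiting replicate 1, 3 to 5 without any 1 sufficient library and 1 with limma-voom, and 16 of 35 splits of the libraries called as many genes.

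Between the positions of Pennellii, 29 genes were higher and 3 lower in the tip at sufficient phosphate (edgeR quasi-likelihood test, adjusted p under 0.05, 4 tips and 3 midsections). The median of all fitted log2 changes lay at -0.38, and RLE scaling gave 88 calls. The groups did not overlap in 6 of the 32 called genes, and in 11.9% of all tested genes, against 5.71% expected by chance. Solyc07g026650.3.1 averaged 874 ± 1572 CPM (SD, n = 4) in the tip against 14.7 ± 14.3 CPM (SD, n = 3) in the midsection, and Solyc04g051500.3.1 averaged 1158 ± 2165 CPM against 23.2 ± 7.97 CPM; the library of 46018 counts held 3230 and 4400 CPM of them. The ratios of the means were 59.4 and 49.9, or 6.01 and 3.27 without that library, and the first was 112 without midsection replicate 3. Solyc09g092260.3.1 was absent from the tips and stood at 42.2 ± 4.78 CPM (SD, n = 3) in the midsection, at least 32.1-fold higher (edgeR adjusted p 0.0184), or 19.1 and 13.7-fold without tip replicates 1 and 3. Solyc04g054740.3.1 had 1 count in the tips and 64.6 ± 5.42 CPM (SD, n = 3) in the midsection, with an edgeR adjusted p of 0.0184. Its means differ 327-fold and its summed counts 138-fold (95% counting interval 24.6 to 5440), or 81.8-fold without tip replicate 1 and at least 19.6-fold without tip replicate 3. The calls for the first 2 genes ended under 7 of 17 alternatives each, that for Solyc09g092260.3.1 under 11 of 18 and that for Solyc04g054740.3.1 under 9 of 18. With only libraries of at least 100000 counts 0 genes were higher and 2 lower in the tip, and 0 were called without tip replicate 2 or without midsection replicate 3 or 4, where 1086 to 1296 genes had an unadjusted p under 0.05. Without midsection replicate 2 the count was 3, and without tip replicate 1 it was 66. Of 35 splits of these libraries, 18 called as many genes.

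The phosphate response differed between the Pennellii positions in 35 genes, 14 higher and 21 lower in the tip (edgeR quasi-likelihood interaction test, adjusted p under 0.05). Solyc03g117340.1.1 and Solyc03g093130.3.1 led the 14 and had no count after rounding in sufficient tips or limiting midsections. In limiting tips they averaged 16 ± 15.1 CPM and 105 ± 161 CPM, and in sufficient midsections 56.8 ± 88.9 CPM and 4.48 ± 6.97 CPM (SD, n = 3 each). Solyc00g016915.1.1 and Solyc07g004997.1.1 led the 21, with 73.97 ± 146.5 CPM and 35.0 ± 63.8 CPM (SD, n = 4) in sufficient tips and 299 ± 533 CPM and 93.1 ± 182 CPM (SD, n = 4) in limiting midsections. In the other 2 groups these genes had at most 2 counts. Their sufficient tip means came mostly from the library of 46018 counts, at 294 and 131 CPM against at most 2.23 and 9.48 CPM in the others. Their limiting midsection means came mostly from the library of 38629 counts, at 1100 and 365 CPM against at most 93.9 and 4 CPM. The calls for these 4 genes, in the order given, ended under 5 of 22, 7 of 22, 5 of 19 and 2 of 15 alternatives. RLE scaling gave 80 calls (12 higher, 68 lower), only libraries of at least 100000 counts gave 10 (6 higher, 4 lower), and leaving out 1 library gave 66, 89 and 114 without sufficient tip replicate 1 and limiting tip replicates 1 and 2, 56 without sufficient midsection replicate 2 and 75 without limiting midsection replicate 2. Of 100 drawn splits, 82 called as many genes.

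Whether the 2 species responded differently was tested as an interaction, since levels of the species come from separate tables mapped to the M82 sequence. The joint fit gave each gene 1 dispersion for both species. The typical biological coefficient of variation was 0.918 in it, against 0.599 in M82 and 1.21 in Pennellii alone. The spread of Pennellii is thus probably understated in these tests. In midsections 8 of 19460 genes differed, 7 with a higher and 1 with a lower response in M82 (edgeR quasi-likelihood interaction test, adjusted p under 0.05). Solyc05g011970.3.1 rose in M82 midsections from 7.73 ± 3.93 CPM to 356 ± 29.9 CPM (SD, n = 4 each), while in Pennellii it stood at 17.3 ± 5.25 CPM (SD, n = 3) and 19.9 ± 4.92 CPM (SD, n = 4). Of its 111 counts in limiting Pennellii midsections, 98 came from 1 library. No library there passed 24.7 CPM, which is below the floor of 78.3 CPM in replicate 3. The small SD is thus no sign of 4 well-measured libraries. The interaction log2 change was 5.39 ± 0.97 (SE, edgeR adjusted p 0.00509) and passed the threshold under all 26 alternatives; the gene was also called up in M82 tips, by 3.88 ± 0.48 on the log2 scale. Solyc11g008820.2.1 averaged 5.599 ± 1.53 CPM and 21.2 ± 7.28 CPM (SD, n = 4 each) at sufficient and limiting phosphate in M82. In Pennellii it averaged 61.9 ± 79.3 CPM (SD, n = 3) at sufficient phosphate and had 2 counts at limiting phosphate (interaction 9.32 ± 1.99, edgeR adjusted p 0.0315), and its call ended under 14 of 26 alternatives. Solyc03g082420.3.1 fell in M82, from 182 ± 57.6 CPM to 10.96 ± 3.94 CPM (SD, n = 4 each), and stood at 3.42 ± 3.67 CPM (SD, n = 3) and 203 ± 327 CPM (SD, n = 4) in Pennellii (interaction -9.64 ± 1.73, edgeR adjusted p 0.00608), a call that ended under 1 of 26 alternatives. Its limiting Pennellii mean was set by replicate 3, a library of 38629 counts, at 693 CPM against 9.75 to 59.5 CPM in the others. Only libraries of at least 100000 counts gave 17 genes, DESeq2 84, and single libraries left out 3 (without sufficient Pennellii replicate 2) to 12, with 4 without sufficient M82 replicate 2, 3 or 4 and 5 without limiting M82 replicate 3. RLE scaling gave 5 with a higher and 2 with a lower response.

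In tips 242 of 19460 genes had a different phosphate response in M82 and Pennellii, 111 higher and 131 lower in M82 (edgeR quasi-likelihood interaction test, adjusted p under 0.05), around a median of -0.54 over all genes that RLE scaling moved to -0.27. As in midsections, 1 dispersion per gene served both species. Solyc07g042690.3.1 and Solyc12g098870.2.1 led the 111, and neither had a count in limiting Pennellii tips. The first averaged 12.3 ± 24.5 CPM and the second 1023 ± 2023 CPM (SD, n = 4 each) in sufficient Pennellii tips, in each case from 1 library for the most part. In sufficient and limiting M82 tips the first averaged 0 and 5.37 ± 9.02 CPM, with 95 of 107 limiting counts in 1 library. The second averaged 2.998 ± 1.84 and 6.66 ± 5.59 CPM there (SD, n = 4 each). Solyc08g006180.3.1 and Solyc07g045357.1.1 led the 131, being absent from sufficient Pennellii tips and at 14.95 ± 13.0 CPM and 61.3 ± 72.8 CPM (SD, n = 3) in limiting ones. In sufficient and limiting M82 tips Solyc08g006180.3.1 averaged 1.39 ± 1.39 and 0 CPM, and Solyc07g045357.1.1 averaged 1.015 ± 1.97 and 0.105 ± 0.122 CPM (SD, n = 4 each). The calls for these 4 genes, in the order given, ended under 16 of 24, 15 of 25, 12 of 24 and 6 of 24 alternatives. RLE scaling changed the split to 143 higher and 101 lower, DESeq2 called 692 genes, limma-voom 27 and a fit of the tips alone 15. Leaving out 1 library gave 49 (without limiting Pennellii replicate 4) to 433 (without limiting Pennellii replicate 1), with 91 to 158 without any 1 M82 tip library or sufficient Pennellii replicate 1 and 409 without sufficient Pennellii replicate 3. Of 80 drawn splits, 10 called as many genes in tips and 4 in midsections.

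Few genes were called in both species. In tips 1 gene rose in both, where independent lists would share 0.539 (Fisher's exact test, one-sided p = 0.419), and in midsections 0 were shared, where 0.138 would be. Of the M82 tip calls tested in both, 139 of 192 rises and 15 of 36 falls had the same sign in Pennellii tips, where the median of all genes lay above 0. Relative to that median, 116 of 192 rises and 24 of 36 falls lay on the same side. In midsections 79 of 152 rises and 46 of 85 falls had the same sign, and 85 and 39 lay on the same side of the median. Genes are not independent, and these shares were not tested. Across the 13188 genes tested in both species, the fold changes had a Pearson correlation of 0.022 in tips and 0.022 in midsections. Simulated data took the depths of the Pennellii libraries and means and dispersions over both positions. In them the test recovered 0% of 4-fold and 40% of 64-fold changes in tips, against 42% and 82% for M82 tips. Shared changes of moderate size could thus be missed in Pennellii. The simulated Pennellii tips gave 1 false call, whereas other splits of the real tip libraries called a median of 97 genes. The simulation thus lacks part of the spread of these libraries, and its rates may not hold for them. Which of depth, dispersion and number of libraries lowered the recovery was not tested. The 4 distinct Pennellii columns under 100000 counts also held 16.6% to 63.4% of the M82 level of genes that are abundant in M82 and low in deep Pennellii libraries, where the 7 libraries of at least 1000000 counts held 2.01% to 5.78% and the 4 libraries in between 4.58% to 6.49%. Of these columns, sufficient tip replicates 2 and 4 (16.6% and 38.6%) and limiting midsection replicate 3 (40.2%) entered the fits. Limiting tips and sufficient midsections had no such library there. Low depth and M82-like levels were thus confounded in part with the groups in every comparison that used Pennellii.

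**Figure D3:**
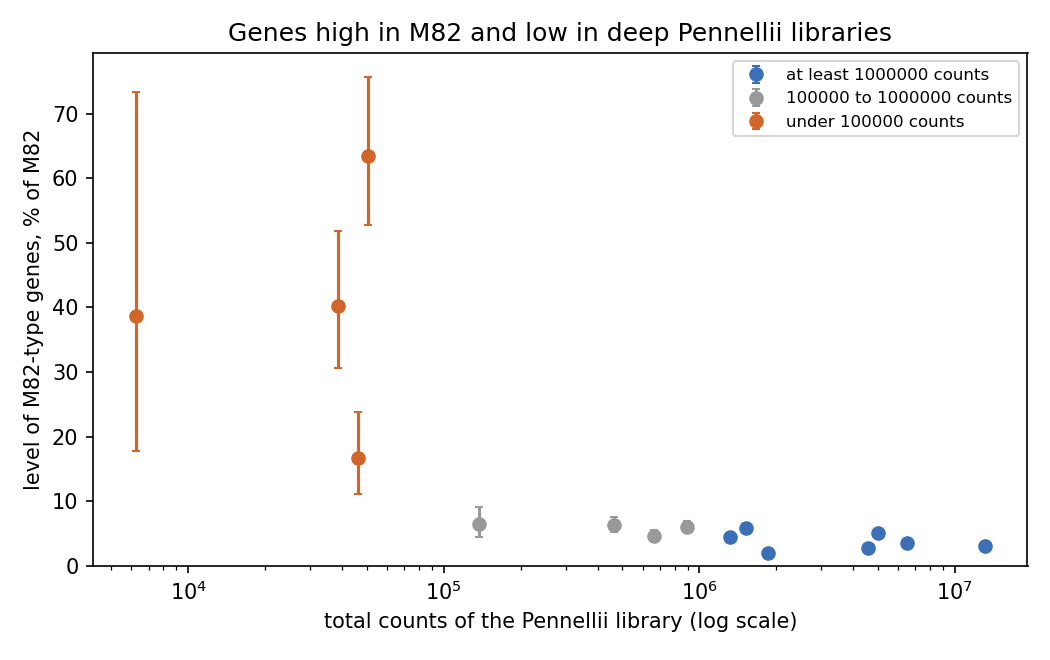
Level of genes that are abundant in M82 and low in deep Pennellii libraries, as a percentage of the M82 mean, against the total counts of each Pennellii library on a log axis; bars are 95% Poisson intervals of the counts and cover counting error only. Libraries of at least 1000000 counts (blue) lie between 2.01% and 5.78%, those in between (grey) between 4.58% and 6.49%, and libraries under 100000 counts (orange) between 16.6% and 63.4%.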

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

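Tests chosen only after a result was seen were the thresholds for genes typical of M82, loosened after a stricter set had left 0 genes, the final number of interaction splits, and the counts without splits that kept whole groups. A library was singled out when its gap to the nearest of the others, relative to the range of its group of 4, passed Dixon's 95% critical value. Chance does that in about 1 of 20 groups of normally distributed values, and 31 of the 85 groups tested had such a library. In 7 of them all other libraries were at 0, where any count is singled out, so the 31 cannot be set against that rate. For total counts these were the sufficient M82 tip replicate 2 at 34103546 against 1406650 to 4456958 in its group, the limiting M82 tip replicate 4 at 9737420 against 4223900 to 4874528, the sufficient M82 midsection replicate 3 at 1084652 against 8454258 to 9095141 and the limiting Pennellii midsection replicate 4 at 4580524 against 38629 to 664429.

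Of the named genes, 27 values stood apart in their group, 16 of them in Pennellii. The Pennellii tip library of 46018 counts held 5 of these: Solyc07g026650.3.1 at 3230 CPM, Solyc04g051500.3.1 at 4400, Solyc12g098870.2.1 at 4060, Solyc00g016915.1.1 at 294 and Solyc07g004997.1.1 at 131 CPM, against at most 153 CPM in the others. The limiting midsection library of 38629 counts held another 5: Solyc08g079160.3.1 at 705 CPM, Solyc07g042190.3.1 at 2610, Solyc00g016915.1.1 at 1100, Solyc07g004997.1.1 at 365 and Solyc03g082420.3.1 at 693 CPM. In the tip library of 6225 counts Solyc09g011160.3.1 stood at 1920 CPM. In deeper Pennellii libraries Solyc12g100300.2.1 stood at 200 CPM and Solyc07g042690.3.1 at 49 CPM in sufficient tip replicate 1, Solyc04g054740.3.1 at 0.79 CPM in sufficient tip replicate 3, and Solyc01g111350.3.1 at 11.4 CPM and Solyc11g008820.2.1 at 0.449 CPM in limiting midsection replicate 4, the other libraries of the last 4 being at 0. In M82 tips, Solyc01g095745.1.1 stood at 1.57 CPM and Solyc06g035610.3.1 at 77.5 CPM in sufficient replicate 4, Solyc03g115380.2.1 at 187 CPM (648 to 682 in the others) and Solyc07g045357.1.1 at 3.96 CPM in sufficient replicate 1, Solyc07g064100.1.1 at 10.3 CPM and Solyc07g042690.3.1 at 18.8 CPM in limiting replicate 2, and Solyc06g061040.3.1 at 0.102 CPM in limiting replicate 4. In M82 midsections, Solyc03g115380.2.1 stood at 1.11 CPM in sufficient replicate 1, Solyc12g088970.1.1 at 43.7 CPM in sufficient replicate 3, Solyc01g111160.3.1 at 0.824 CPM in limiting replicate 3 and Solyc11g045520.2.1 at 2.04 CPM in limiting replicate 4.

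Differences of the phosphate response between groups were tested as interactions and gave 177 genes between the positions of M82, 35 between those of Pennellii, 242 between species in tips and 8 in midsections. Other splits of the same libraries show how many genes are called when the groups are mixed. For M82 tips and midsections, the real split was the only 1 of 35 to call as many genes, 260 and 261 against at most 4 and 6. For tip against midsection it called 4992 against at most 48. A share of 1 in 35 is the smallest these splits can give and falls under a bound of 5%. The bound was not adjusted for the 10 comparisons, so chance is unlikely for these but not excluded. For the M82 interaction 2 of 100 drawn splits called as many as the real 177. The other one, with 376 genes, exchanged the complete midsection groups and so tested the sum of both responses; apart from splits that kept both groups of a position whole, 1 of 97 called as many, the real one, and the highest other count was 1. The share of 2 in 100 fell under the bound of 5%, but only in this larger draw. A smaller first draw had the same 2 splits and did not fall under 5%, and the number was raised after that was seen. Apart from whole exchanges, these splits mix the phosphate groups within each position, which blurs both responses and not only their difference. They cannot tell whether the 177 exceed chance for the difference itself. In Pennellii chance cannot be excluded: 19 of 35 splits called as many as the 92 genes in tips (highest other 191), 16 of 35 as many as the 16 in midsections (highest 47), 18 of 35 as many as the 32 between positions (highest 139) and 82 of 100 as many as the 35 of the interaction (highest 182). For the species differences, 10 of 80 splits called as many as 242 in tips (highest 614) and 4 of 80 as many as 8 in midsections (highest 16), so by the same bound on all splits chance cannot be excluded there either. Without splits that kept both groups of a position or species whole, 81 of 99 called as many for the Pennellii interaction, 9 of 77 for the species difference in tips and 2 of 75 for that in midsections. The last share, 2.67%, is under 5%, so the result for species in midsections depends on whether such splits count. These splits mix the phosphate groups too, so a low share could not exclude chance for a difference of responses. Whether a structure among the Pennellii libraries that does not follow the groups gave the high counts of some splits was not tested. Low depth did follow the groups in part. In the fits, libraries under 100000 counts were found only among sufficient tips and limiting midsections of Pennellii.

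The 4 distinct Pennellii columns under 100000 counts resembled M82. In them 32 genes, of at least 20 CPM on average and 5 CPM in each M82 library and at most 5% of the M82 mean in the pooled deep Pennellii libraries, stood at a median of 39.4% of the M82 level, from 9 to 122 counts per column, against at most 5.78% in the 7 deep libraries, each left out when its own genes were chosen. Low depth alone was argued against by thinning: these columns correlated more with M82 than with deep Pennellii across genes, by a median difference of 0.055, whereas deep libraries thinned to the same depths gave -0.161 to -0.049. M82 RNA or M82 reads in these libraries is a candidate explanation that both values meet, and whether it entered before or during sequencing cannot be read from counts. No biological explanation was tested, nor whether these columns account for the high counts of some splits.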

How the results depend on the processing

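The alternatives on library depth, on the identical columns, on genes with whole counts and on genes shared by both M82 positions were chosen after seeing the data; the others were planned. The planned tests of gene lists, with their alternatives, were not run, because the IDs carry no descriptions. In M82, RLE scaling, both filter settings, the replicate block, whole-count genes and libraries of at least 2000000 counts left all 5 counts of genes within 1.5 times of those reported. Replicate numbers were not taken to pair the samples, which would need a correlation over 0.1 of the deviations across genes in every same-numbered pair. These lay at -0.036 to 0.098 in M82 and -0.063 to 0.215 in Pennellii, where 3 of 18 same-numbered pairs exceeded 0.1, against 1 of 55 others. As a hint from the data, 9 of 16 M82 and 9 of 14 Pennellii libraries correlated best with their own number. The number expected by chance was not computed. A pairing of only part of the libraries could fail that rule and stays open. With that replicate block, calls were 258 in M82 tips and 264 in midsections, but 8 in Pennellii tips, 4 in midsections, 7 for position by phosphate, 4 for tip against midsection and 51 for the species difference in tips and 7 for that in midsections. With DESeq2, calls were 544 in M82 tips, 613 in midsections, 546 for position by phosphate and 56 shared by both positions, 43 in Pennellii tips, 18 for position by phosphate there, and 692 and 84 for the species differences in tips and midsections. With limma-voom, they were 455, 672 and 65 shared in M82, 0 in Pennellii tips, 1 in midsections, 0 for position by phosphate (663 genes at an unadjusted p under 0.05), 2 for tip against midsection and 27 for the species difference in tips. Fits of only the groups compared gave 157 in M82 tips, 439 in midsections and 3272 for tip against midsection, 44 and 61 for Pennellii tips and tip against midsection, and 15 and 34 for the species differences. Without a low-count filter the counts were 51 in Pennellii midsections, 92 for position by phosphate, and 563 and 110 for the species differences; at 5 CPM in 4 libraries they were 179 in Pennellii tips and 8 in midsections. RLE scaling gave 80 for Pennellii position by phosphate and 88 for tip against midsection, and moved the median of all log2 changes from 0.64 to 0.045 and from -0.38 to -0.084 there, from -0.15 to 0.084 in Pennellii midsections and from 0.26 to 0.064 for the species difference in midsections.

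Only Pennellii libraries of at least 100000 counts gave 12 calls in tips, 5 in midsections, 10 for position by phosphate, 2 for tip against midsection and 17 for the species difference in midsections. The identical columns kept in both groups gave 143 in Pennellii tips and 56 for tip against midsection; kept as midsection only they gave 32 in midsections, 54 for position by phosphate and 64 for tip against midsection. Single libraries left out gave ranges of 173 to 238 in M82 tips, 119 to 308 in midsections, 100 to 289 for position by phosphate and 4264 to 4945 for tip against midsection. In Pennellii they gave 6 to 189 in tips, 2 to 25 in midsections, 29 to 114 for position by phosphate and 0 to 66 for tip against midsection, and for the species differences 49 to 433 in tips and 3 to 12 in midsections. Of 281 values of named genes under alternatives in M82 comparisons, 211 stayed past the threshold and 70 did not; of 446 in comparisons with Pennellii, 290 did and 156 did not. The direction was the same in all 727. The cause of these changes was not tested, except that fewer libraries or genes entered where the setting removes them.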

Other observations

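The comparison of positions at limiting phosphate, the split of sufficient tip libraries between measures, the counts of genes above 20% and below 5% and the spans that treat genes without a count apart were chosen after the results had been seen. At limiting phosphate 1908 M82 genes differed between tip and midsection, 1128 higher and 780 lower in the tip (edgeR quasi-likelihood test, adjusted p under 0.05, n = 4 and 4), against 4992 at sufficient phosphate, and the test of the difference itself called 177. Of the 4992, 1647 were called in the same direction at limiting phosphate and 8 in the opposite one. Their log2 differences at limiting phosphate followed those at sufficient phosphate with a slope of 0.481, and 92.8% were smaller. Choosing the genes at sufficient phosphate lowers that slope and raises that share by itself.

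Genes specific to the midsection at sufficient phosphate stood at uneven levels in limiting tips. Of 13 genes with at most 0.5 CPM on average in sufficient tips and at least 20 CPM in both kinds of midsection, 6 stood above 20% of their limiting midsection level in limiting tips and 5 below 5%, of which 2 had no count there.

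Expression in limiting M82 tips lay towards the midsection. The sufficient tip libraries that enter both measures do not account for all of it: the correlation across genes of the tip response with the difference between positions was -0.479 with shared libraries, still -0.179 or lower in all 6 splits of them between the measures, and with any 1 sufficient tip library left out the median stayed at -0.159 or lower. Midsections moved towards tips as well, with correlations of 0.474 with shared libraries and 0.132 to 0.253 in splits. Midsection RNA mixed into limiting tip libraries, as the whole cause, would give the midsection genes 1 common ratio, but their ratios spanned 87.7-fold between the 10th and 90th percentiles, 51-fold with the 2 genes without a count set to 3 counts over the group and 13.7-fold without them, against at most 2.70-fold between limiting midsection libraries. Other technical explanations, such as the lower depth of some sufficient libraries, were not tested, so the cause stays open; a change in root growth that could place different zones of the root in the same segment was not tested either, as root lengths are not given in the sources used here.

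Called genes of M82 lay beside one another in the ID order more often than shuffled calls did. Of neighbouring tested genes, 11 pairs in tips and 9 in midsections were called in the same direction, where 10000 shuffles gave 2.78 and 2.06 on average (permutation p = 0.0005 and 0.0002). Among genes with whole counts in every M82 library, 2 pairs were found in each position, where shuffles gave 1.87 and 1.24 on average (permutation p = 0.6 and 0.4). Reads shared between neighbouring copies are thus a candidate explanation of the excess, if fractional counts mark shared reads, which was not tested. Leaving out genes with fractional counts may also leave out recent copies that respond together, so a common response of such copies stays open.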
